A study of Mus musculus with 4 samples.

How the data were processed

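Gene expression was measured in mandibular molar tooth germs of NMRI mouse embryos at embryonic day 14, which were kept in organ culture for 24 h with 1 µM TCDD (2,3,7,8-tetrachlorodibenzo-p-dioxin) or with the solvent DMSO at 0.65%. Per the labels, each RNA sample pooled about 60 explants from 3 experiments, and each was hybridised to 1 murine U74v2A oligonucleotide array. The series holds 4 arrays, 2 per group. Biotin-labelled cRNA was made from 11 µg of total RNA for replicate 1 of both groups, from 7 µg for DMSO replicate 2 and from 8 µg for TCDD replicate 2, per the labels' protocols. The culture label of DMSO replicate 2 is the only one of the 4 that lists ascorbic acid in the medium.

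The deposited values are hybridisation intensity signals of the MAS5 algorithm, 1 per probe set and array, on a linear scale. Per the labels, the authors used Affymetrix Microarray Suite 5.0 and scaled each array to a target signal of 100. No probe-level files and no detection calls were used here, so nothing says which probe sets were above background on an array. The depth of an array has no count, and the number of arrays limits the precision.

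The deposited table carries a spreadsheet fault that no label mentions. Of its 49952 cells, 18515 (37.1%) hold the serial number of a calendar day in place of a signal, because a value such as 12.3 was read as a day and a month. These cells were turned back into a signal, with the day as the whole part and the month as the decimal. The repair was checked on the values. Each array holds 273 distinct serials, and every other value is at most 6479.9, far below any serial. No value that could be read as a day and month was left among the remaining decimals between 1 and 32. After the repair, the mean signal with 2% trimmed at each end was 100.05 on each of the 4 arrays, which is the stated target. The fault touched 6113 of 12488 probe sets, all at signals under 32.

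Probe sets were named from the platform annotation, with symbols looked up through Entrez IDs in the gene table of the GRCm38.p6 assembly. Of the 12488 probe sets, 66 are Affymetrix controls, 10855 have 1 symbol, 396 have several and 1193 have none. Of those with 1 symbol, 10839 matched the gene table and 0 changed their symbol. They stand for 8252 genes. The files name no genome build, so no coordinates are given.

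The comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a trend of variance on mean) on log2(signal + 16), over the 5783 probe sets with a mean signal of at least 50 across the 4 arrays. Control probe sets were left out, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. All fold changes are on the log2(signal + 16) scale, which understates the change of dim genes. The fit had 8.8 prior degrees of freedom and 10.8 in total. As a measure that does not need a variance estimate, probe sets were counted whose ratio of signal + 16 was at least 2 in the same direction in all 4 TCDD-DMSO array pairs. An exact permutation test over 2 arrays against 2 cannot give a two-sided p under 0.33 and was not run.

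Before the data were examined, 26 gene lists were fixed, 20 for pathways and tissues of the tooth and 6 for other cell types. Each gene was represented by its probe set with the highest mean signal. Lists with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry. Camera compares the genes of a list with all other genes, so higher or lower for a list means relative to these. With an estimated correlation, camera takes its degrees of freedom from the few arrays and not from the number of genes. Few lists could pass in that form, and a call lost there does not show that gene correlation undid it. Adjustment ran over the 22 lists tested. The naming rule was also fixed before the data were examined. It takes genes past the adjusted p, then fills up to 24 with the genes whose smallest change over the 4 array pairs is largest, raised and lowered in equal numbers as far as possible, then every measured gene of the aryl hydrocarbon receptor battery, and up to 4 members with the smallest p of a list that passes its test or up to 3 of any other list described. Genes named outside this rule are marked as chosen after their values were seen.

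Simulated data sets, 10 of TCDD against DMSO, had the means of the 5783 probe sets, 200 of them changed, and their variances as shrunk by eBayes. The procedure was tested on these data. It recovered 22.4% of 1.5-fold, 80.6% of 2-fold and 100% of 4-fold changes, all in the right direction, with 10.8 false calls per data set. The noise was drawn independently for each probe set, without any structure by replicate number. In the real data 4 probe sets passed, so the adjusted cut-off was stricter than with 200 changed, and these shares do not carry over. In 20 simulated data sets the list test called a list shifted by 0.5 on the log2 scale in 100% and an unshifted list in 0%. Genes were drawn without correlation, so the 0% does not carry over to lists whose genes vary together. Estimated correlations of the real lists ran from -0.19 (endothelium) to 0.98 (skeletal muscle). The 1 list called in the real data had a mean change of 0.3, below the simulated 0.5.

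The alternatives were other offsets of 1 and 64, no filter or a mean signal of at least 100, quantile normalization, scaling by the median, eBayes without the trend or with robust estimation, each array left out in turn, the replicate number as a block, an adjusted p of 0.1, a smallest ratio of 1.5, an estimated correlation in the list test, and the mean over a gene's probe sets in place of the brightest. Added after the data had been seen were leaving out the probe sets with serials, setting serials to 16, using the table as deposited, and testing lists with at least 3 measured genes. Leaving out 1 array sets 1 replicate number against both, so treatment and replicate number are then partly confounded. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.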

Results

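Expression was profiled in mouse molar tooth germs at about the cap stage of development, after 24 h in organ culture with 1 µM TCDD, a dioxin that binds the aryl hydrocarbon receptor, or with the DMSO solvent. There were 2 arrays per group, each from a pool of about 60 explants. The comparison asks which transcripts of the tooth germ differ after exposure to TCDD. Signals are in MAS5 units with a target of 100, and errors of signals are SDs over 2 arrays.

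Cyp1a1 and Cyp1b1, xenobiotic-metabolising cytochrome P450 genes and classical targets of the aryl hydrocarbon receptor, rose in the TCDD-treated tooth germs. Cyp1a1 (94715_at) went from a signal of 13.7 ± 1.41 (SD, n = 2) in DMSO to 203 ± 11.1 (SD, n = 2) in TCDD, a log2 change of 2.88 ± 0.22 (SE) with a limma adjusted p of 3.7e-04. Cyp1b1 (99979_at) went from 88.2 ± 14.7 to 487 ± 45.9 (SD, n = 2 each), a log2 change of 2.28 ± 0.21 (SE) with a limma adjusted p of 9.2e-04. Both were higher in all 4 TCDD-DMSO array pairs, with smallest log2 changes of 2.78 and 2.04. Both DMSO signals of Cyp1a1, 14.7 and 12.7, lie below the offset and were among the values stored as day serials, so its log2 change rests on the repair and on the offset, with 3.79 at an offset of 1 and 1.78 at 64. For Cyp1b1 these were 2.46 and 1.86. Each gene has another probe set on the array, below the filter: that of Cyp1a1 (161831_at) had mean signals of 18 in DMSO and 17 in TCDD, and that of Cyp1b1 (161368_r_at) had 1.15 and 0.05.

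The other genes of the receptor's battery were also higher where they could be measured, but not past the test over all probe sets. Tiparp, which encodes a TCDD-inducible poly(ADP-ribose) polymerase, had signals of 61.1 and 57.1 in DMSO and of 147.8 and 271.3 in TCDD, a log2 difference of 1.53 ± 0.27 (SE) with a limma adjusted p of 0.167. Its log2 change was 1.94 without TCDD replicate 1, past the limma test with an adjusted p of 0.00631, and 1.13 without TCDD replicate 2, where the adjusted p was 0.436. Without DMSO replicate 1 or 2 Tiparp did not pass either (limma adjusted p 0.515 and 0.236). Nqo1, a quinone reductase (94351_r_at), differed by 0.99 ± 0.26 on the log2 scale, with a limma adjusted p of 0.997, while its other, dimmer probe set (94350_f_at) differed by 0.22. With the replicate number as a block, Tiparp and Nqo1 did pass (limma adjusted p 3.0e-11 and 0.0049). That fit pooled all variances into a common trend, and no label says that the numbers pair the samples. Of the 14 listed battery genes, 12 were on the array and 4 reached the filter. All 4 were higher, 2 past the limma threshold over all probe sets and 4 adjusted over the list alone. As the filter takes the mean over all arrays, the TCDD signals brought in Cyp1a1 and Nqo1, whose DMSO means were under 50. Of the 8 genes below the filter, which the naming rule does not cover and which are named after their values were seen, 3 were higher and 5 lower in TCDD, and 0 passed limma's adjusted p without the filter. With 4 measured genes the list was under the minimum of 5 for the list test. Without the filter it had 12 genes and passed (limma's camera adjusted p 9.3e-07, or adjusted p = 0.913 with an estimated correlation). Among those below the filter, Ahrr, the receptor's repressor, had signals of 22.1 and 23.8 in DMSO and 38.5 and 54.2 in TCDD. Cyp1a2 had mean signals of 12.8 and 6.1, Aldh3a1 (99548_at) of 31.4 and 29.4, and Selenbp1 of 34 and 44.6. Gsta1, Gsta2, Serpinb2 and Xdh had means under 50 in both groups.

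**Figure D1:**
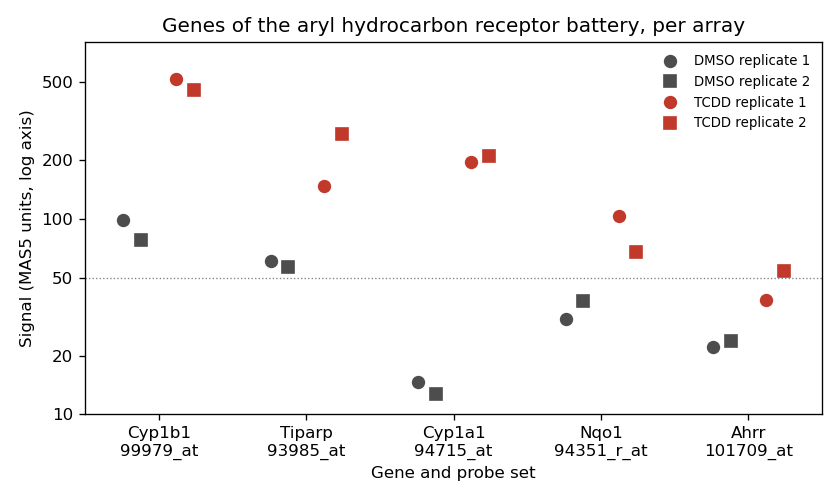
Signal in MAS5 units (log axis) of 5 genes of the aryl hydrocarbon receptor battery on the 2 DMSO arrays (grey) and the 2 TCDD arrays (red), 1 point per array, with the filter of 50 as a dotted line. Each TCDD point lies above both DMSO points of its gene, from 194.8 and 210.5 against 14.7 and 12.7 for Cyp1a1 to 38.5 and 54.2 against 22.1 and 23.8 for Ahrr, whose mean over the arrays is below the filter. Ahrr was added after the values were seen, and of the 8 battery genes below the filter it has the largest difference, while 5 were lower in TCDD.

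Genes of the receptor complex itself showed no change past the test. Ahr, the receptor, had mean signals of 56.6 in DMSO and 51.4 in TCDD, a log2 difference of -0.11 ± 0.23 (SE). Nrip1, a nuclear receptor co-regulator, differed by 0.46 ± 0.2 (SE). The list had 3 measured genes, under the minimum of 5 for the list test, and did not pass with a minimum of 3.

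Across all 5783 probe sets tested, 4 passed an adjusted p of 0.05 in limma, 2 raised and 2 lowered. At an unadjusted p under 0.05 there were 150 (81 higher, 69 lower). Chance gives 289 for arrays with no other structure, but these had one, as the split by replicate number gave 740, so the 2 counts cannot be compared directly. The 2 lowered were a probe set of Ift46, an intraflagellar transport gene, and 96082_at. The Ift46 probe set 161949_at fell from signals of 107.4 and 76.6 to 17.2 and 8.2, a log2 change of -1.92 ± 0.28 (SE, n = 2) with a limma adjusted p of 0.0383. The brighter probe set of the same gene (97423_at) did not pass, at 123 ± 10.9 in DMSO and 137 ± 3.61 in TCDD (SD, n = 2 each). The probe set 96082_at, annotated to both Mrpl30 and Gm6238 and so not assigned to a gene, fell from 280 ± 40.2 to 84.9 ± 1.27 (SD, n = 2 each), a log2 change of -1.55 with a limma adjusted p of 0.0251. The call of 96082_at was lost without DMSO replicate 1, DMSO replicate 2 or TCDD replicate 2 (limma adjusted p 0.0516, 0.109 and 0.0606) and without the filter (0.188). The Ift46 call was lost with an offset of 1 (limma adjusted p 0.0792), without the filter (0.928), without TCDD replicate 2 (0.152) and with the day serials, which hold both of its TCDD signals, set to 16 (0.0536), and without either DMSO array its mean signal was below the filter.

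In 5 probe sets the ratio was at least 2 in all 4 array pairs, 3 raised (Cyp1a1, Cyp1b1 and Tiparp) and 2 lowered. At a ratio of 1.5 there were 15, 11 raised and 4 lowered. With 1 array left out only 2 pairs have to agree instead of 4, an easier condition. The count at a ratio of 2 was then 5 and 25 without DMSO replicates 1 and 2, and 7 and 14 without TCDD replicates 1 and 2. The counts of 25 and 14 came with a replicate 1 array alone in its group, set against both replicate numbers. The arrays of the groups did not overlap in 1726 probe sets (29.8%), 883 higher and 843 lower in TCDD, where chance gives 33.3% for arrays with no other structure.

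Other genes were named for a large difference in all 4 array pairs and did not pass the limma test in the fit without a block for replicate number. Krtap3-1, a hair keratin-associated protein gene, had mean signals of 29.2 in DMSO and 78.2 in TCDD, a log2 difference of 1.06 ± 0.24 (SE). Gjb2, which encodes the gap junction protein connexin 26, differed by 0.98 ± 0.24, Krt81, a hair keratin gene, by 0.86 ± 0.21, and Klf5, a transcription factor of proliferating epithelia, by 0.84 ± 0.21 (SE). The 3 other probe sets of Krt81, all below the filter, differed by -0.45, -0.16 and -0.02. At the probe sets in the fit, the limma adjusted p-values of Krtap3-1, Gjb2, Krt81 and Klf5 lay between 0.804 and 0.997. Iigp1, an interferon-inducible GTPase gene, differed by 0.84 ± 0.22, and Ccl2, which encodes a monocyte-attracting chemokine, by 0.8 ± 0.23 (SE). Another probe set of Iigp1 (103963_f_at), below the filter, differed by 0.25. Fndc1, Zfp148 and Ash2l had log2 differences of 0.68, 0.72 and 0.83. Each of these was higher in all 4 array pairs.

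Among genes lower in all 4 array pairs, Copb2, which encodes a subunit of the coatomer coat of transport vesicles (93341_r_at), had mean signals of 695 in DMSO and 328 in TCDD, a log2 difference of -1.03 ± 0.2 (SE) with a limma adjusted p of 0.288. Its other probe set (93340_f_at) had mean signals of 162 and 188. Rgs16, a regulator of G-protein signalling, differed by -0.87 ± 0.23, Tspo2 by -0.75 ± 0.23 and Dcaf12 by -0.74 ± 0.21 (SE). Atp5pb, a subunit gene of the mitochondrial ATP synthase, differed by -0.74, Txnrd3 by -0.69, Imp4 by -0.63, Tuba8 by -0.6, Naa38 by -0.5 (-0.19 at its other probe set, 161860_f_at) and Bcl7c by -0.45. None of these passed the limma test in the fit without a block for replicate number.

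**Figure D2:**
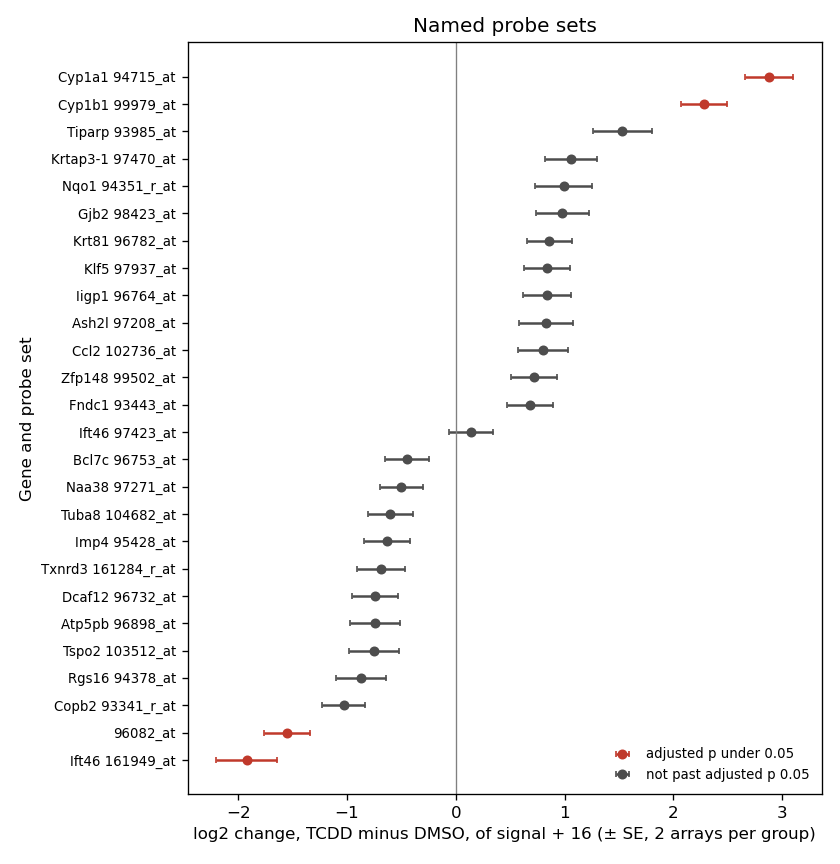
The log2 change of signal + 16 in TCDD against DMSO (x axis, bars are ± SE from limma, 2 arrays per group) for 26 probe sets chosen by size of change and by the test, with those past an adjusted p of 0.05 in red. Cyp1a1 at 2.88 and Cyp1b1 at 2.28 stand apart on the raised side, and the 2 Ift46 probe sets lie at -1.92 and 0.14.

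Of the 22 gene lists tested, 1 passed. Macrophage markers were higher as a group: all 9 measured of 14 listed were higher, none past the test on its own, over all probe sets or adjusted over the list alone. Their mean log2 change was 0.3, with a camera adjusted p of 0.00639 from limma. The call was lost with an estimated correlation (limma's camera adjusted p = 0.787), and fry gave an adjusted p of 0.511. The estimated correlation of the list, -0.07, lay below the preset 0.01, so correlation between its genes does not account for the loss in camera. Members with the smallest p were Ctss, a lysosomal cysteine protease gene, at 0.58 ± 0.23, Lyz2, a lysozyme gene, at 0.59 ± 0.24, and the complement genes C1qb at 0.53 ± 0.23 and C1qc at 0.35 ± 0.2 (SE, log2). Another probe set of C1qb (162276_i_at), below the filter, had mean signals of 49 in DMSO and 20.8 in TCDD, and another of Lyz2 (162309_at) differed by -0.31. Without DMSO replicate 2 or without TCDD replicate 2 the call was lost (limma's camera adjusted p 0.245 and 0.0521), with mean changes of 0.24 and 0.31. Without the filter, over all 14 listed genes, the mean was 0.17 (limma's camera adjusted p 0.0128, or adjusted p = 0.934 with an estimated correlation).

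Lists of the dental tissues did not pass with all arrays. Of the 12 measured genes of the dental and oral epithelium, 10 were higher and 0 passed on their own (mean log2 change 0.18, camera adjusted p 0.125 from limma). Perp, a desmosome gene, differed by 0.61 ± 0.21, Dsp, which encodes desmoplakin, by 0.38 ± 0.2, and Cdh1, which encodes E-cadherin, by -0.44 ± 0.21 (SE). Of the 15 measured genes of the dental mesenchyme 7 were higher, with a mean of 0.03 and an adjusted p of 0.917. Its members with the smallest p were Bmp4 (93456_r_at), at 0.42 ± 0.23, Dlx3, at 0.42 ± 0.27, and Barx1, at -0.33 ± 0.22 (SE). The other probe set of Bmp4 (93455_s_at) differed by 0.17. Of 9 measured enamel knot signals, the genes of the epithelial signalling centre of the tooth, 3 were higher and 6 lower (mean -0.07, adjusted p 0.917). Fst, which encodes the activin antagonist follistatin, differed by 0.56 ± 0.22 and Fgf4 by -0.47 ± 0.22 (SE). Cdkn1a, the cell cycle inhibitor p21, had signals of 559.1 and 85.7 in DMSO and of 75.4 and 107.2 in TCDD, so that its log2 difference of -1.19 ± 0.58 (SE) rests on DMSO replicate 1. Its other probe set (94881_at) had mean signals of 72.6 and 75.3. Without TCDD replicate 1 the median log2 changes of the epithelium and the mesenchyme lists were 0.25 and 0.26. Without TCDD replicate 2 that of the enamel knot list was -0.35. Leaving out 1 array sets 1 replicate number against both. Replicate 1 minus replicate 2 gave means of -0.1, -0.25 and -0.2 for these lists, so the shifts cannot be told apart from a difference by replicate number.

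Signalling lists also stayed short of the threshold with all arrays and the filter. In TGF-beta and BMP signalling 12 of 18 measured genes were higher (mean 0.13, camera adjusted p 0.125 from limma), among them Tgfb1 at 0.44 ± 0.21 and Tgfb2 at 0.45 ± 0.22 (SE). In FGF signalling 4 of 6 were lower (mean -0.17, adjusted p 0.263), with Spry4, a feedback inhibitor of FGF signalling, at -0.66 ± 0.26 (SE). EGF receptor signalling had 5 of 6 genes higher (mean 0.16, adjusted p 0.312). In Wnt and Hedgehog signalling 6 of 14 were higher (mean -0.04, adjusted p 0.745). Dkk1, which encodes a Wnt antagonist, differed by -0.71 ± 0.27 and Wnt4 by 0.49 ± 0.24 (SE). Retinoid metabolism had a mean of -0.07 and an adjusted p of 0.733, with Rxrb, a retinoid X receptor gene, at -0.66. TGF-beta and BMP signalling passed as higher without the filter (limma's camera adjusted p 0.0128, or adjusted p = 0.964 with an estimated correlation). Its median log2 change was 0.21 without TCDD replicate 1, and that of Wnt and Hedgehog signalling was -0.27 without TCDD replicate 2. Replicate 1 minus replicate 2 gave means of -0.18 and -0.37 for these lists, so neither shift can be told apart from a difference by replicate number.

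For matrix genes, 15 of 22 measured collagen and basement membrane genes were higher (mean 0.08, camera adjusted p 0.431 from limma), with Col6a2 at 0.41 ± 0.19 and Col1a2 (101130_at) at 0.36 ± 0.18 (SE). The other probe set of Col1a2 (161156_r_at) differed by -0.38. Mineralised matrix genes had 6 of 7 higher (mean 0.15, adjusted p 0.236). Col1a1, the main collagen gene of dentin and bone, differed by 0.25 ± 0.15 (SE) at 94305_at and by -0.18 at its other probe set (103709_at). With the probe sets of a gene averaged the mean of the mineralised matrix list was 0.05 (limma's camera adjusted p 0.886). Without TCDD replicate 2 it was 0.33. Replicate 1 minus replicate 2 gave a mean of 0.26 for this list, so that shift cannot be told apart from a difference by replicate number. Matrix proteases and inhibitors had a mean of -0.02 (adjusted p 0.846) and ascorbate-dependent collagen modification one of -0.04 (adjusted p 0.745).

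Lists of growth and stress did not pass either with all arrays and the filter. Proliferation genes had 11 of 24 higher (mean -0.04, camera adjusted p 0.603 from limma). Tk1, the thymidine kinase gene of dividing cells, differed by -0.52 ± 0.23 (SE), and Top2a, a topoisomerase gene, by 0.27. Cell cycle arrest and apoptosis genes had 10 of 16 higher (mean -0.01, adjusted p 0.846), with Cdkn1c at 0.37 ± 0.18 (SE). The oxidative stress response had 8 of 15 higher (mean 0.03, adjusted p 0.866). Sod1, a superoxide dismutase gene, differed by 0.41 ± 0.19 and the metallothionein gene Mt1 by -0.42 ± 0.22 (SE). Immediate early and heat shock genes had 12 of 16 higher (mean 0.15, adjusted p 0.165), with Dusp1 at 0.45 ± 0.21 (SE). Cholesterol synthesis had 11 of 12 lower (mean -0.1, adjusted p 0.236), and hypoxia and glycolysis had 6 of 11 lower (adjusted p 0.846). Immediate early and heat shock genes passed as higher without the filter (limma's camera adjusted p 0.0128, or adjusted p = 0.979 with an estimated correlation). Their median log2 change was 0.27 without TCDD replicate 1, and that of hypoxia and glycolysis was -0.23 without DMSO replicate 1. Replicate 1 minus replicate 2 gave means of -0.2 and -0.43 for these lists, so neither shift can be told apart from a difference by replicate number.

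Among markers of other cell types, skeletal muscle genes had 5 of 6 higher (mean 0.19, camera adjusted p 0.65 from limma), endothelial genes 4 of 6 lower (mean -0.15, adjusted p 0.429), and red blood cell genes 3 of 5 higher (mean -0.01, adjusted p 0.859). The median log2 change of the muscle list was 0.44 without DMSO replicate 1 and 0.73 without TCDD replicate 2. Leaving out 1 array sets 1 replicate number against both. These shifts cannot be told apart from a difference by replicate number, as replicate 1 minus replicate 2 gave a mean of 0.99 for this list. Pecam1, an endothelial adhesion gene, differed by -0.61 ± 0.3 (SE) and Emcn, which encodes endomucin, by 0.35. Cartilage genes (3 measured) and nerve and glia genes (2 measured) were under the minimum of 5 for the list test, with means of -0.18 and -0.03. With a minimum of 3 the cartilage list was tested and did not pass. In 4 lists the mean, the median and the direction of camera differed in sign or stood at 0: cell cycle arrest, red blood cell, hypoxia and dental mesenchyme. No gene of any list but Cyp1a1 and Cyp1b1 passed over all probe sets.

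**Figure D3:**
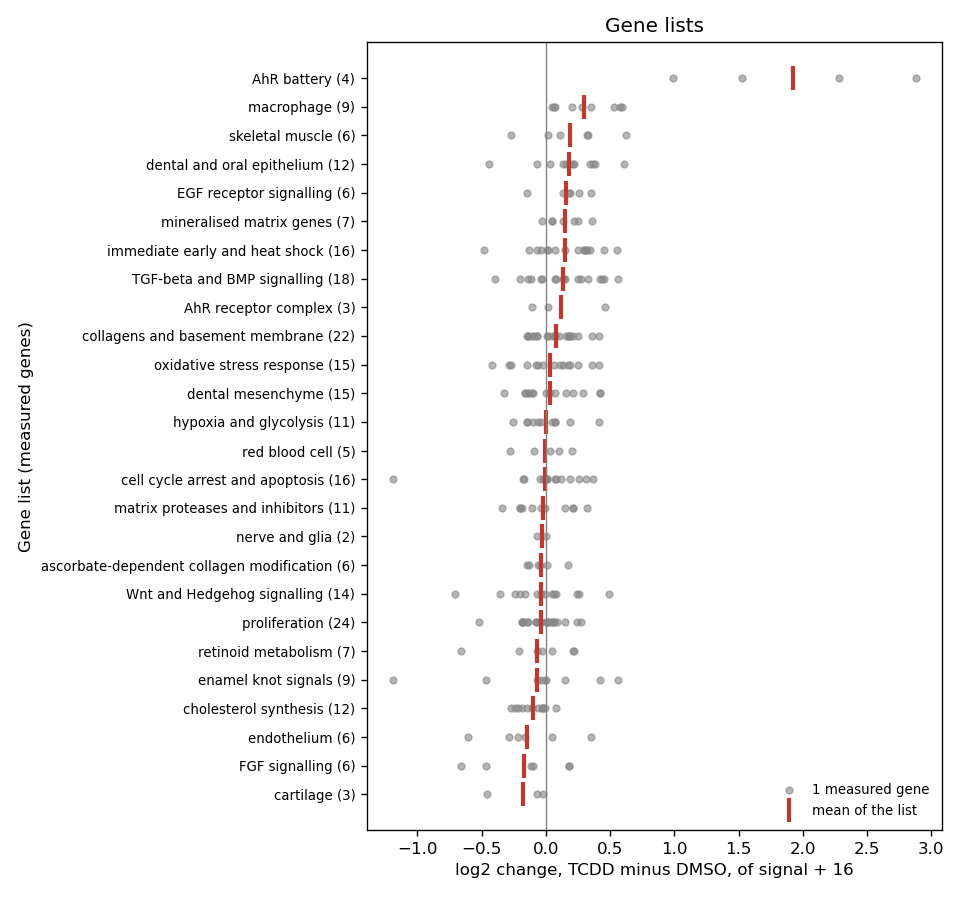
The log2 change of signal + 16 in TCDD against DMSO for each measured gene (grey points) of 26 gene lists, with each list's mean as a red bar and its number of measured genes in brackets. The aryl hydrocarbon receptor battery has the highest mean, and the macrophage list follows at 0.3 with its 9 genes above 0.

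The arrays differed in ways that the treatment does not mark. Across probe sets, which are not independent replicates, the correlation of log2 signals was 0.951 between the DMSO arrays and 0.953 between the TCDD arrays, 0.983 between DMSO replicate 2 and TCDD replicate 2, and 0.945 between DMSO replicate 1 and TCDD replicate 1. The pairs of unlike number across groups had 0.941 and 0.952. All 9 probe sets of the bacterial and phage control RNAs were higher on both replicate 1 arrays than on both replicate 2 arrays, by a median factor of 2.21, while TCDD over DMSO gave a median of 0.908. The 3′ to 5′ ratio of the Gapdh control was 1.13 on TCDD replicate 1, against 0.765 and 0.807 on the DMSO arrays and 0.779 on TCDD replicate 2. The actin ratio was 1.1 and 1.13 in DMSO and 1.23 and 1.08 in TCDD. The 3′ Gapdh control had signals of 2334.6 and 2869 in DMSO and 2150.3 and 2494 in TCDD, and the 3′ actin control 4956 and 6053.9 in DMSO and 4343.4 and 5184.7 in TCDD.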

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

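All tests of explanations in this part were chosen after the results had been seen. Outside the 5783 probe sets of the fit lay 6639 dim ones. Among them 10 were at least 1.5-fold higher (signal + 16) in all 4 TCDD-DMSO array pairs and 19 lower. The split of the arrays by replicate number gave 66 such probe sets in either direction and the crossed split 12. The 10 stood out because their signal in TCDD lay above the level of the DMSO control arrays and they were outside the fit. Without the filter all 10 were tested and 0 passed limma's adjusted p. Their mean signals in DMSO and TCDD were 33.1 and 63.6 for Lgals3bp, 18.6 and 43 for Ifit3, 8.2 and 30.6 for Usp18, 6.05 and 27.8 for Ifi204, 8.05 and 24 for Msr1, and 3.45 and 21.6 for Slpi. The other 4 were Foxq1 at 4.35 and 18.8, Gmip at 9 and 28, Rab35 at 8.6 and 24.8, and Recql5 at 4.15 and 15.9. With no detection calls, nothing shows which of these signals were above background.

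The macrophage list was higher in TCDD by camera at the preset correlation only (limma's camera adjusted p 0.00639, or adjusted p = 0.787 with an estimated correlation), and the call was lost without DMSO replicate 2 (0.245) or TCDD replicate 2 (0.0521). For the case that it holds, 2 biological explanations were weighed: more macrophages in the TCDD pools, or an interferon response. More macrophages would raise all markers alike; the SD of the 9 changes (0.22) divided by their mean standard error was 0.998, so the changes were no more spread than their errors, and neither a common rise nor separate ones could be excluded. For an interferon response, a list of interferon and antigen presentation genes was tested, without Iigp1, Gbp3, B2m, Ctss and Ccl2, whose values had been seen (all higher in TCDD): 10 of 13 measured genes were higher, with a mean of 0.19, a limma camera p of 0.00322 at the preset correlation and of 0.27 with an estimated one. With 1 array left out its mean ran from 0.1 without TCDD replicate 2 to 0.28 without TCDD replicate 1. The 2 explanations cannot be told apart with 2 arrays per group.

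The lower signals of Ift46 and Copb2 rested on 1 probe set each. For Ift46, the other, brighter probe set did not fall, with a log2 change of 0.14 ± 0.2 (SE). This argues against a lower level of the whole transcript only if both probe sets read Ift46, which was not checked. The gap of 2.05 ± 0.34 (SE, taking the 2 as independent) may be widened, as the lower probe set was picked for its fall. With the 2 TCDD cells at the highest signal a serial can stand for under the repair rule, 31.8, the log2 change was -1.16. Both DMSO signals lay above 31.8, so the sign could not have turned. The value limits how much of the fall could come from a wrong day or month, but does not test the rule itself. For Copb2 the other probe set lay 1.21 ± 0.34 (SE) above, but its name marks probes shared with other transcripts, so a fall of the gene and an effect on 1 probe set cannot be told apart. A change in part of the transcript, or in another RNA that these probes bind, stays open, as no probe sequences were used here.

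Krtap3-1, Krt81, Gjb2 and Klf5, with a median log2 difference of 0.92, could be higher because the TCDD pools held more epithelium, or because suprabasal differentiation had advanced. The epithelial list fixed in advance had a mean of 0.18 ± 0.08 over its 12 measured genes (SE over genes, not over pools). This lay below 0.46, the median divided by 2 to allow for the choice of the 4 genes by their size. That divisor was set after the values were seen, and how far the choice raised the median is not known. The values therefore cannot decide whether a larger share of epithelium was the whole cause, and a small rise in share stays open as well. For differentiation, a list of cornified and suprabasal genes left out the 4 and also Krt13, Krt1, Lgals3 and Perp, whose values had been seen (log2 differences of 0.81, 0.73, 0.66 and 0.61, in the direction of the idea). It had 13 of 20 measured genes higher, with a mean of 0.12 and a limma camera p of 0.0775, or 0.221 with an estimated correlation. That mean depended on single arrays, from 0.05 without DMSO replicate 1 to 0.22 without DMSO replicate 2 or without TCDD replicate 1. Differentiation therefore stays an open hypothesis.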

How the results depend on the processing

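The alternatives that concern the day serials, and lists of at least 3 genes, were chosen after the data had been seen. Cyp1a1 and Cyp1b1 were called under every alternative that tested them, except with the table as deposited, which treats serials as signals. The number of probe sets past the adjusted p (4) was 2 without the filter. It was also 2 (Cyp1b1 and 96082_at) with the probe sets holding serials left out, which removed Cyp1a1 and the Ift46 probe set. It was 139 with the table as deposited, with 0 shared, and between 2 and 5 with 1 array left out, with 2 without DMSO replicate 1 and 2 without TCDD replicate 2. With 1 array left out, the lone array is assumed to vary like the others, and treatment is partly confounded with replicate number. With the replicate number as a block, whose fit pooled all variances into a common trend, it was 32 (18 raised, 14 lowered), all 4 included, and Tiparp, Cdkn1a, Copb2, Gjb2, Krtap3-1, Nqo1, Krt81, Klf5, Rgs16, Iigp1, Ccl2, Ash2l and Dcaf12 were also called, although the same-numbered pairs of Cdkn1a go opposite ways (-2.65 and 0.28). The deviations of same-numbered arrays correlated at 0.38 across probe sets, and the spike controls and muscle genes follow the number. No label says that the numbers pair the samples and 2 pairs are too few to show it, so the pairing stays open. The number changed 2-fold in all pairs (5) was 3 with an offset of 64, 3 with serials left out, 315 with the table as deposited, 15 at a ratio of 1.5, and between 5 and 25 with 1 array left out, where only 2 pairs have to agree, with 25 without DMSO replicate 2 and 14 without TCDD replicate 2. The number of lists past the threshold (1) was 4 without the filter, 0 at a mean signal of at least 100, where the macrophage list had 4 measured genes and was not tested, 0 with the table as deposited, 0 with an estimated correlation, 2 with at least 3 measured genes, where the receptor battery joined with an adjusted p of 3.1e-19 (limma's camera, 0.273 with an estimated correlation), and between 0 and 5 with 1 array left out: 3 without DMSO replicate 1, 0 without DMSO replicate 2, 5 without TCDD replicate 1 and 4 without TCDD replicate 2. Other shifts of these counts stayed within 1.5 times.

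With the table as deposited the log2 change turned to -7.48 for Cyp1a1, -3.86 for Krtap3-1, -3.86 for Nqo1, -4.02 for Ash2l and 8.5 for the Ift46 probe set 161949_at, and the list means to 0.4 for Wnt and Hedgehog signalling, 0.39 for proliferation and -0.83 for macrophages, since serials exceed every signal. For lists, direction means that of camera, which compares a list with the other genes and so can turn while the mean keeps its sign. Without the filter, the median log2 change over all probe sets was -0.05. In 7 cases the mean alone turned, and the cause of each turn was not tested. Camera's direction turned with a mean of the same sign for ascorbate-dependent collagen modification with the table as deposited (mean -0.14), for enamel knot signals (-0.02), Wnt and Hedgehog signalling (-0.05) and endothelium (-0.03) without the filter, for dental mesenchyme (0.01) with quantile normalization and for cell cycle arrest (-0.01) with the replicate block. The mean turned as well for mineralised matrix genes without the filter (-0.05), for oxidative stress at a mean signal of at least 100 (-0.01) and for red blood cells with quantile normalization (0.03). Of the values recomputed, 1151 kept their direction and side of the threshold or stayed in range. With 1 array left out, Cdkn1a ranged from -2.44, where it was called, to 0.06, and list means from -0.08 to 0.13 for oxidative stress, -0.28 to 0.17 for enamel knot signals, -0.1 to 0.2 for dental mesenchyme, 0 to 0.29 for EGF receptor signalling, -0.28 to 0.18 for Wnt and Hedgehog signalling, -0.03 to 0.33 for mineralised matrix, -0.18 to 0.11 for ascorbate-dependent collagen modification, -0.1 to 0.03 for proliferation, -0.13 to 0.1 for cell cycle arrest, -0.25 to 0.26 for hypoxia and glycolysis, -0.15 to 0.01 for retinoid metabolism, -0.14 to 0.83 for skeletal muscle and -0.17 to 0.15 for red blood cells.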

Other observations

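The arrays also differed by replicate number across both groups, most in skeletal muscle genes. This comparison and its genes were chosen after the values were seen. The skeletal muscle list, with 6 measured genes, was higher on the replicate 1 arrays, by a mean log2 difference of 0.99 and with 6 of 6 genes higher (limma camera adjusted p 6.1e-08, or adjusted p = 0.413 with an estimated correlation). Actc1, which encodes cardiac alpha-actin and is expressed in embryonic skeletal muscle, had signals of 457.2 on DMSO replicate 1 and 612.4 on TCDD replicate 1, against 152.3 and 180.3 on the replicate 2 arrays. Of 28 muscle probe sets on the array, with dim ones included, 20 were higher on both replicate 1 arrays and 2 were lower. The mineralised matrix list did not pass, with 5 of 7 genes higher (mean 0.26, limma camera adjusted p 0.0848, or adjusted p = 0.608 with an estimated correlation). Of single genes, Ibsp, the bone sialoprotein gene, had 1029.2 and 1053.6 against 479.6 and 446.7, and Scx, a transcription factor gene of tendon, had 154.4 and 163.6 against 79.3 and 78.1.

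In the other direction, hypoxia and glycolysis genes were lower on the replicate 1 arrays, 11 of 11, by a mean of -0.43 (limma camera adjusted p 5.1e-06, or adjusted p = 0.413 with an estimated correlation), and 11 of 14 Wnt and Hedgehog genes were lower, by a mean of -0.37 (adjusted p 0.0011, or adjusted p = 0.413 with an estimated correlation). Dental mesenchyme genes were also lower, 12 of 15 with a mean of -0.25 (limma camera adjusted p 0.0256), as were 6 of 9 enamel knot signals (mean -0.2) and 5 of 5 red blood cell genes (mean -0.27), both with a limma camera adjusted p of 0.0455, and all 3 lists had an adjusted p = 0.434 with an estimated correlation. Shh, the signal of the dental epithelium and its enamel knot, had 79.5 and 60.8 on the replicate 1 arrays against 162.1 and 184.2. Ly6d had 110.3 and 112.7 against 241.7 and 282.9, and the desmosomal gene Dsc3 had 30.5 and 24.2 against 86 and 85.5. None of these single genes passed limma's adjusted p, the nearest being Actc1 at 0.0584. The labels give no reason why the pools differ, apart from the RNA input of 11 µg for replicate 1 and 7 or 8 µg for replicate 2, and no explanation was tested.

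The 4 arrays can be split into 2 and 2 in 3 ways, too few for a share under 0.05. The real split gave 4 probe sets past the adjusted p and the highest other split gave 1, so that 1 of 3 splits gave as many. For a ratio of at least 2 in all 4 pairs the real split gave 5 and the split by replicate number gave 11, so that 2 of 3 splits gave as many. At an unadjusted p under 0.05 the split by replicate number gave 740 probe sets against 150, which points to a structure of the samples that follows the replicate number.

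Among the 19 dim probe sets that were at least 1.5-fold lower (signal + 16) in all 4 pairs, 2 were singled out after their values were seen. Lgi4 had signals of 78 and 64.7 in DMSO and 6.3 and 15.8 in TCDD, and Esr1, the estrogen receptor alpha gene, had 39.4 and 42.6 in DMSO and 7.5 and 13.4 in TCDD. Without the filter only Cyp1a1 and Cyp1b1 passed limma's adjusted p, so neither Lgi4 nor Esr1 did. With no detection calls, nothing shows which of these signals were above background.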
